A study of Mus musculus with 4 samples.

How the data were processed

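Transcripts of single hematopoietic stem cells (HSCs) from mouse bone marrow were counted in 4 libraries, made from long-term HSCs (LT-HSC) and short-term HSCs (ST-HSC) of 2 male mice aged 14 weeks. The mice carried a Tie2-driven inducible Cre (Tie2-bG-Micm) and a YFP reporter, per the labels. The libraries were prepared with the 10x Chromium 3' v3 chemistry, per the labels' protocols. This droplet method gives each droplet a barcode and each captured RNA molecule a unique molecular identifier (UMI), so that copies of 1 molecule are counted once. Group and mouse number came from the labels. Per the series record, both gates took cells that lack lineage markers and CD48 and carry Kit and Sca-1; cells with CD150 (Slamf1) were sorted as LT-HSC and cells without it as ST-HSC.

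The deposited values were raw UMI counts per gene and barcode. They were made with Cell Ranger 3.1.0 and the mm10 genome build, per the submitters' processing notes, while the software version in the matrices was 3.0.2, per the file headers. How barcodes were chosen for the deposited matrices is not given in the sources used here. The count tables listed 31053 genes, and 35 symbols stood for more than 1 gene identifier. Identifiers were looked up in the GENCODE vM21 annotation of the same genome assembly, where 30934 were found (99.6%) and 30468 of these had the same symbol. Counts of 3' tags can be shared between near-identical genes, so single members of the globin, histone, ribosomal protein and histocompatibility families are uncertain.

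Barcodes were kept as cells when they had at least 1000 genes, at least 2000 UMIs and at most 10% of UMIs from mitochondrially encoded genes. This kept 22 of 39553 barcodes in LT-HSC of mouse 1, 1217 of 1288 in LT-HSC of mouse 2, 2633 of 2793 in ST-HSC of mouse 1 and 1707 of 1784 in ST-HSC of mouse 2. The cell filter, the gene lists, the cell type markers, the rule for naming genes and the tests were fixed before the data were examined. Because the filter removed most of the first library, all its barcodes summed together were used as an alternative added after the data had been seen. That alternative is given beside the results below as the values with all barcodes of LT-HSC of mouse 1. Summed over kept cells, the libraries held 115305, 13249904, 27870823 and 13566531 UMIs in the same order. At 3 counts, the detection floor was 26.0 counts per 1e6 (CPM) in LT-HSC of mouse 1 and 0.226, 0.108 and 0.221 CPM in the others. Intervals and floors cover counting error only.

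Raw counts were summed over the kept cells of each library, since cells are not replicates, and the 4 sums were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM normalization, filterByExpr defaults, gate as the only factor). Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Log2 fold changes are LT-HSC minus ST-HSC, and standard errors (SE) were computed as the size of the log2 fold change divided by the square root of F. CPM values in the gate comparison use the TMM-scaled totals, and group values are given as mean ± SD over 2 libraries. Plain totals were used for the floors, for Slamf1 outside the cell filter and for values inside or outside the neutrophil-lineage cluster. They were also used for the mouse comparison of Fbp1, Hist1h2ap and Nme2. For genes below the floor of LT-HSC of mouse 1, the LT-HSC mean and SD include a library that can hardly show them. For a gene with 0 UMIs in a group, a lower bound against 3 counts over the group is given, and for 1 to 3 UMIs a ratio with its 95% counting interval. Gene lists were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01. Of 31 lists, 26 had 5 or more tested members. Camera with an estimated correlation and fry were run beside it. DESeq2 1.42.0 was the alternative count test.

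The rule for naming genes took the 4 gate genes, then the 12 genes with the largest fold change in each direction among those past the threshold with a mean of 20 CPM or more and the same direction in both mice. From each list it took up to 4 members with the smallest p and a mean of 5 CPM or more, which gave 113 genes in all. Other genes named below were chosen after their values were seen.

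On counts simulated from the means and sizes of these libraries, the gate test on kept cells recovered 84% of 100 genes changed by 1 on the log2 scale and 100% of 100 genes changed by 2. It made 9 false calls among 12342 genes tested. The changed genes were drawn from those with a mean of 20 CPM or more, and the simulated spread was the one fitted to these libraries. Mouse effects and stray cells were not simulated. The recovery therefore does not cover genes below 20 CPM, and the false calls do not cover those sources of error. With all barcodes of LT-HSC of mouse 1, the same simulation recovered 94% and 100%, with 16 false calls among 12719 genes. The mouse numbers pair the libraries, since libraries with the same number came from the same animal, per the labels. Deviations from the gate means had a correlation of 0.142 across 6256 genes between libraries of the same mouse, and of -0.203 across 6086 genes with all barcodes of LT-HSC of mouse 1. A fit with the mouse number as a block was run as an alternative. Replicates were not copies of each other: chi-square per degree of freedom was 1.46 for the LT-HSC pair on kept cells, 21.8 for that pair with all barcodes of mouse 1, and 22.9 for the ST-HSC pair.

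Kept cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, with 0.5 and 2 as alternatives), giving 15 clusters. Clusters were named from the marker lists by a scoring rule set after the data had been seen: at least 3 markers detected in 10% of the cells, at least 2 among the 10 leading genes and a mean log2 fold over 1. Scrublet in scanpy called 31 of 5579 cells doublets; it did not run on the library of 22 cells, and doublets were kept in the main values. To compare single cells across depths, each cell was thinned to 2000 UMIs at random with a fixed seed. A cell score was the mean log count of 50 genes minus that of 50 others, chosen by their fold in the other mouse with a pseudocount of 5 CPM. Shares carry exact Clopper-Pearson 95% intervals. Alternatives covered normalization, filters on genes and cells, doublets, clusters, depth, cell number, the test used, the block and each library left out in turn. Groups of 2 libraries are too small for a test of single outlying libraries or for counting other splits of the samples.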

Results

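LT-HSC, which can rebuild blood for the life of a recipient, and ST-HSC, which do so for a limited time, were sorted from the bone marrow of the same 2 mice and profiled as single cells. There were 2 libraries per gate and 4 in all. The median kept cell held 4494.5 UMIs in LT-HSC of mouse 1, 10367 in LT-HSC of mouse 2, 9881 in ST-HSC of mouse 1 and 7504 in ST-HSC of mouse 2. The library of LT-HSC of mouse 1 stood apart, with a median of 285 UMIs over its 39553 barcodes and 22 barcodes that passed as cells. The kept cells of the LT-HSC group therefore come almost entirely from mouse 2.

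**Figure D1:**
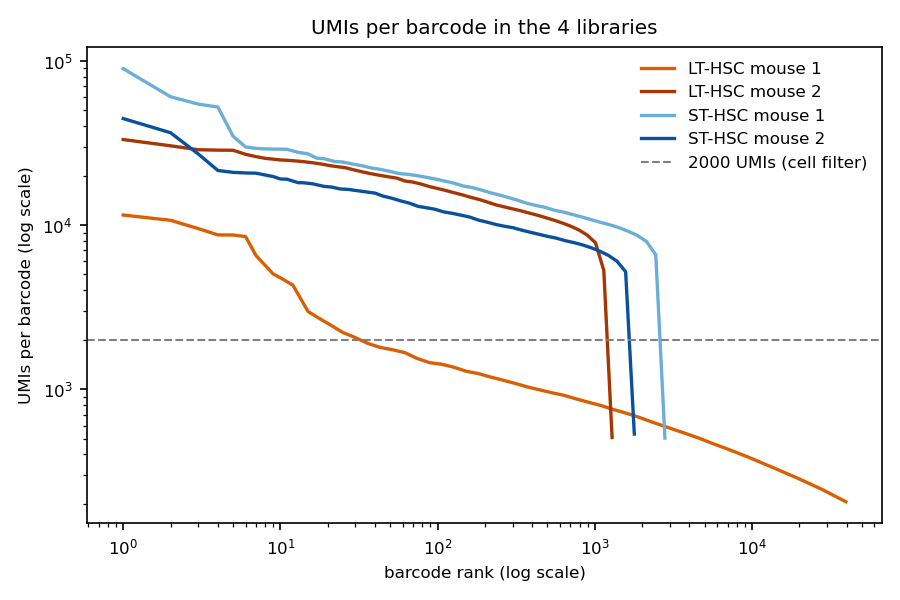
UMIs per barcode (log scale) against barcode rank (log scale), with 1 line per library and the cell minimum of 2000 UMIs dashed. The LT-HSC library of mouse 1 holds 39553 barcodes with a median of 285 UMIs, while the other libraries have medians of 10149.5, 9694 and 7412.5 UMIs.

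The first comparison asked which transcripts differ between the gates. Slamf1, the gene for the CD150 protein on which the gates part, lay at 27.5 ± 7.36 CPM in LT-HSC and 1.14 ± 0.434 CPM in ST-HSC (n = 2 each), a log2 fold change of 4.43 (SE 0.33). The kept cells of LT-HSC of mouse 1 held 4 Slamf1 UMIs. With all barcodes of that library, LT-HSC lay at 17.9 ± 4.64 CPM and the log2 fold change was 4.15 (SE 0.30). Cd48 was lower in LT-HSC, by -2.82 (SE 0.34). Kit (0.12, SE 0.20) and Ly6a, which encodes Sca-1 (-0.14, SE 0.20), mark both gates and did not pass the test, with edgeR adjusted p of 0.985 and 0.970. In the mm10 assembly, Slamf1 lies on chromosome 1 from 171767127 to 171801184 and Cd48 on the same chromosome from 171682009 to 171705258.

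Among the genes higher in LT-HSC, the sulfotransferase gene Sult1a1 had the largest fold change by the naming rule (3.84, SE 0.23), at 47.4 ± 9.18 CPM against 3.68 ± 0.0498 CPM. The lectin receptor gene Clec1a followed at 3.31 (SE 0.24) and the imprinted noncoding RNA Meg3 at 2.88 (SE 0.19). Apoe, which encodes a lipid carrier, lay at 557 ± 140 CPM against 115 ± 16.4 CPM (2.35, SE 0.20). The transcriptional repressor gene Gfi1b (1.97, SE 0.23) and Socs2, a feedback inhibitor of cytokine signalling (1.94, SE 0.21), were higher too. Cracr2b (2.66), Slfn2 (2.56), Tgm2 (2.23), Cpne8 (2.20), Mtss1l (2.01) and Bex4 (1.98) completed the 12 genes.

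Among the genes higher in ST-HSC, Flt3, the receptor tyrosine kinase of multipotent and lymphoid progenitors, lay at 148 ± 16.8 CPM against 11.5 ± 4.72 CPM in LT-HSC (-3.33, SE 0.23). The leukocyte surface genes Cd53 (-3.21, SE 0.27) and Cd52 (-3.07, SE 0.23), the chemokine gene Ccl3 (-3.59, SE 0.29), Slc16a11 (-4.71, SE 0.33), Wfdc17 (-4.55, SE 0.26) and Tespa1 (-4.42, SE 0.32) differed in the same direction. So did 5 genes of neutrophil granules. Mpo, which encodes myeloperoxidase, lay at 44.1 ± 11.6 CPM in ST-HSC (-6.55, SE 0.40). Elane, the gene of neutrophil elastase, had 2 UMIs in LT-HSC and 2650 in ST-HSC, a ratio of 427 (counting interval 118 to 3531). Most of these Elane UMIs, 1809 of 1852 in mouse 1 and 787 of 798 in mouse 2, lay in cells of the neutrophil-lineage cluster. Outside the clusters of other types Elane had 1 UMI in LT-HSC and 42 and 11 UMIs in ST-HSC, and Mpo differed by -3.76 (SE 0.54). Over all its barcodes LT-HSC of mouse 1 held 68 Elane UMIs, and the Elane log2 fold change was -4.44 (SE 0.57). Camp (-7.02), Ngp (-5.27) and Lcn2 (-4.02) differed widely between the ST-HSC libraries, at 33.9 and 109, 15.8 and 92.7, and 12.2 and 60.1 CPM in mice 1 and 2. All barcodes of LT-HSC of mouse 1 together held Camp at 63.3 CPM (768 UMIs) and Ngp at 27.8 CPM (338 UMIs). Both lay above ST-HSC of the same mouse, so the direction was reversed there, and below ST-HSC of mouse 2. On kept cells, LT-HSC of mouse 1 had 0 UMIs of Camp and Ngp. The rule of the same direction in both mice therefore rested on those 0 UMIs in mouse 1. Lcn2 lay at 7.25 CPM over all those barcodes, below both ST-HSC libraries.

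**Figure D2:**
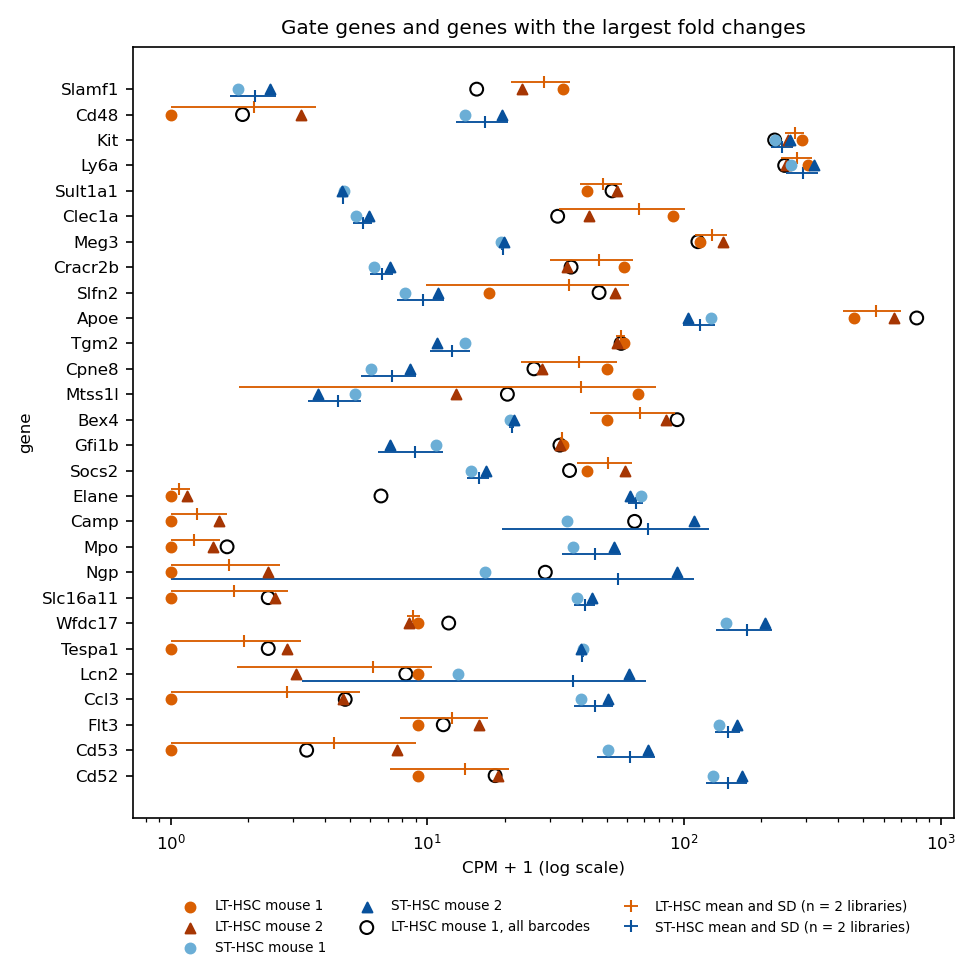
CPM + 1 per library (log scale) for the 4 gate genes and the 12 genes with the largest fold changes in each direction. Filled points are libraries, open circles are all barcodes of LT-HSC of mouse 1, and crosses with bars are the mean and SD of 2 libraries. Slamf1 lies at 32.7 and 22.3 CPM in LT-HSC and at 0.83 and 1.44 CPM in ST-HSC.

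In all, edgeR called 455 genes higher in LT-HSC and 396 higher in ST-HSC of 12656 tested, against 1718 genes at an unadjusted p under 0.05. DESeq2 on the same sums called 28 and 24; of the 24 genes above it called 18 and not Slfn2, Cpne8, Gfi1b, Socs2, Ngp and Lcn2. Nor did DESeq2 call Cd48 or, among genes named below, Il12a, Cebpa, S100a8, Prss34, Mcpt8, Gp9, Plek, Cdkn1c, Ndn, Hoxb2, Hoxb5, Btg2, Fos, Hbb-bs, Hba-a1, Hba-a2, Nusap1, Cdk1, Trp53inp1, Iigp1 and Ifi27l2a. Without LT-HSC of mouse 2 the counts were 1 and 0 (1080 at an unadjusted p under 0.05), and the 1 gene, named after its value was seen, was F830016B08Rik (3.71, SE 0.33). With all barcodes of LT-HSC of mouse 1, edgeR called 650 and 493 of 12892 genes and DESeq2 457 and 393. Of the edgeR calls, 397 and 343 genes were shared with the calls on kept cells and 0 lay in the opposite direction. The fits on kept cells and on all those barcodes differ only in that library. The overlap, also for the 24 genes, is therefore no independent check. Of the 24 genes above, the 12 higher in LT-HSC and 10 of the 12 higher in ST-HSC passed with all barcodes, and Camp (adjusted p = 0.622, range over alternatives 1.34e-94 to 0.987) and Ngp (adjusted p = 0.284, range 5.93e-68 to 0.965) did not. Without LT-HSC of mouse 2, 0 of the 24 passed on kept cells, and 21 passed with all barcodes of LT-HSC of mouse 1 (not Camp, Ngp and Lcn2). DESeq2 on all those barcodes called 20 of the 24 and not Elane, Camp, Ngp and Lcn2. In fits with every library each p rests on 2 animals per gate, and the same 2 mice gave both gates. On kept cells, mouse 1 adds only 22 cells to LT-HSC. Fits without LT-HSC of mouse 2 rest on 1 animal in that gate.

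The lists of stem and progenitor genes parted by gate. Of 25 genes known to be enriched in HSCs, 14 rose in LT-HSC, 0 in ST-HSC and 11 did not pass (17 adjusted over the list alone: 16 and 1). Among these genes, Mllt3 lay at 291 ± 40.0 CPM against 93.1 ± 0.361 CPM (1.57, SE 0.19). The list passed camera at an adjusted p of 1.23e-17, and had an adjusted p = 0.512 with an estimated correlation. Of 15 multipotent progenitor genes, 12 rose in ST-HSC and 3 did not pass (14 adjusted over the list alone). Plac8 (-2.14, SE 0.22), Cd53 and Cd52 were among them. That list had an adjusted p of 7.73e-16, and p = 0.512 adjusted with an estimated correlation.

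Genes of lineage priming were higher in ST-HSC. Of 9 tested lymphoid priming genes, 7 rose in ST-HSC (7 adjusted over the list alone) and 2 did not pass. Ighm, the heavy chain of immunoglobulin M, lay at 33.1 ± 0.738 CPM against 0.231 ± 0.327 CPM. LT-HSC of mouse 1 had 0 Ighm UMIs, and LT-HSC of mouse 2 alone lay at 0.462 CPM. Dntt, the DNA polymerase that adds bases to antigen receptor joints, had 1 UMI in LT-HSC and 465 in ST-HSC, a ratio of 150 (counting interval 26.8 to 5937). The cytokine subunit gene Il12a differed less (-0.90, SE 0.21). The list had a camera adjusted p of 1.86e-07, and p = 0.512 adjusted with an estimated correlation. Of 18 myeloid priming genes, 11 rose in ST-HSC and 7 did not pass (14 adjusted over the list alone). Cebpa, the factor that directs granulocyte fate, lay at 14.1 ± 0.0116 CPM against 0.501 ± 0.708 CPM (-3.81, SE 0.41), and Ctsg at 31.5 ± 14.4 CPM against 0.193 ± 0.272 CPM. Both had 0 UMIs in LT-HSC of mouse 1 and lay at 1.00 and 0.385 CPM in LT-HSC of mouse 2. The camera adjusted p was 9.29e-13, and p = 0.512 adjusted with an estimated correlation. The count and the camera p include the neutrophil-lineage cells, and the list holds Mpo, Elane and Ctsg. Of the Mpo UMIs in ST-HSC, 815 of 993 in mouse 1 and 609 of 688 in mouse 2 lay in those cells. With the clusters of other types left out, Cebpa differed by -3.74 (SE 0.42), and Ctsg had too few counts to be tested.

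Markers of mature neutrophils moved with these genes: 6 of 8 rose in ST-HSC and 2 did not pass (8 adjusted over the list alone). S100a8, a calcium-binding protein of neutrophils, lay at 231 and 872 CPM in ST-HSC of mice 1 and 2. The list had a camera adjusted p of 0.000188, and p = 0.700 adjusted with an estimated correlation. Cells in the neutrophil-lineage cluster made up 0.164% of LT-HSC of mouse 2 (2 of 1217 cells), 0.494% of ST-HSC of mouse 1 (13 of 2633) and 1.29% of ST-HSC of mouse 2 (22 of 1707). At a clustering resolution of 0.5 these shares were 0.657%, 0.987% and 1.93%, and no cluster had the name of macrophages; at 2 they were as at 1. With the clusters of other cell types left out, 9 of the 12 genes highest in ST-HSC passed the test; Camp did not, and Ngp and Lcn2 had too few counts to be tested. S100a8 did not pass there either (-0.96, SE 0.36). Mast cell and basophil genes rose in ST-HSC for 3 of 5 members (5 adjusted over the list alone). Prss34 and Mcpt8, proteases of basophils, had 0 UMIs in LT-HSC and were at least 91.6-fold and 49.0-fold higher in ST-HSC. The ST-HSC libraries of mice 1 and 2 differed, at 8.38 and 47.1 CPM for Prss34 and 3.50 and 27.3 CPM for Mcpt8. With the clusters of other types left out, Prss34, Mcpt8 and the myeloid gene Ctsg had too few counts to be tested. The list had a camera adjusted p of 0.00266, and p = 0.700 adjusted with an estimated correlation.

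Genes of megakaryocytes and platelets were mostly higher in LT-HSC. Of 15 tested members, 11 rose in LT-HSC, 1 in ST-HSC and 3 did not pass (12 and 1 adjusted over the list alone). Vwf, the gene of von Willebrand factor, lay at 27.9 ± 6.82 CPM against 3.34 ± 0.435 CPM (2.84, SE 0.28). The platelet receptor subunit gene Gp9 (1.47, SE 0.22) was higher too, and Plek was lower (-1.24, SE 0.23). Without LT-HSC of mouse 2, Gp9 changed sign (-0.36). The camera adjusted p was 2.14e-11, and p = 0.390 adjusted with an estimated correlation. Of 12 imprinted genes, 6 rose in LT-HSC and 6 did not pass (7 and 1 adjusted over the list alone). Besides Meg3 these included Cdkn1c, an inhibitor of cyclin-dependent kinases, at 72.9 ± 1.06 CPM against 25.4 ± 1.31 CPM, Grb10 (1.62, SE 0.21) and Ndn (1.28, SE 0.21). That list had a camera adjusted p of 2.39e-08, and p = 0.390 adjusted with an estimated correlation. Of 15 Hox genes, which encode developmental transcription factors, 5 rose in LT-HSC (6 and 1 adjusted over the list alone), among them Hoxb2 (1.74, SE 0.22) and Hoxb5 (1.56, SE 0.28). Its camera adjusted p was 0.000188, and p = 0.512 adjusted with an estimated correlation.

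**Figure D3:**
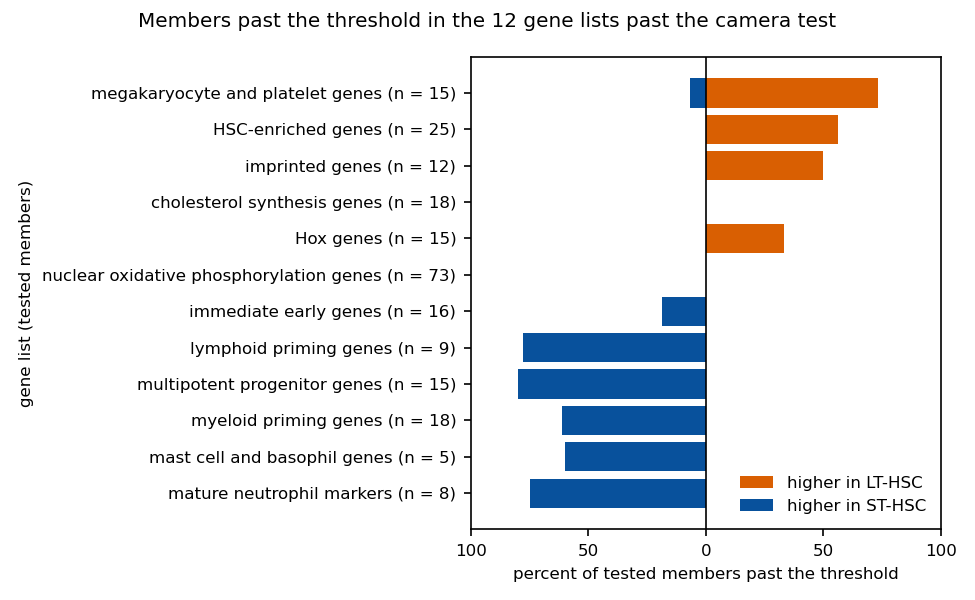
Percent of tested members past the edgeR threshold, higher in LT-HSC (right) or in ST-HSC (left), for the 12 lists past camera at an inter-gene correlation of 0.01. Of 25 HSC-enriched genes 14 were higher in LT-HSC, and of 15 multipotent progenitor genes 12 were higher in ST-HSC.

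Another 3 lists passed camera with few or no single members past the threshold. Of 16 immediate early genes, 3 rose in ST-HSC (4 adjusted over the list alone), among them Btg2 (-1.75, SE 0.25) and Fos (-0.84, SE 0.21), at a camera adjusted p of 0.0142 and p = 0.629 adjusted with an estimated correlation. The 73 nuclear oxidative phosphorylation genes had a median log2 fold change of -0.11 and 0 members past the edgeR threshold (0 adjusted over the list alone). Their camera adjusted p was 0.000435, with p = 0.845 adjusted with an estimated correlation, and their median was 0.10 with all barcodes of LT-HSC of mouse 1. The 18 cholesterol synthesis genes had a median of 0.34 and 0 members past the threshold (0 adjusted over the list alone), at a camera adjusted p of 0.0405 and p = 0.845 adjusted with an estimated correlation. Without LT-HSC of mouse 2, Fos (0.10) and the cholesterol synthesis list (median -0.80) changed sign. With an estimated correlation, 0 of the 12 calls held (2 lists, the megakaryocyte and imprinted genes, had an unadjusted p under 0.05), and fry called 0 lists, with a lowest adjusted p of 0.458. With all barcodes of LT-HSC of mouse 1, camera called 11 lists, 9 of them among the 12. The immediate early, oxidative phosphorylation and cholesterol synthesis lists were lost, and the S phase and cytosolic ribosomal protein lists passed, both toward LT-HSC (both at an adjusted p = 0.788 with an estimated correlation). On the same barcodes fry called 5: the HSC-enriched, multipotent progenitor, lymphoid priming, megakaryocyte and imprinted genes.

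The remaining 14 lists did not pass camera. Erythroid genes went both ways, with 2 of 14 higher in LT-HSC and 6 higher in ST-HSC (2 and 6 adjusted over the list alone; camera adjusted p = 0.726). Car1 had 0 UMIs in the kept cells of LT-HSC and was at least 58.2-fold higher in ST-HSC, at 17.4 and 4.41 CPM. Over all its barcodes LT-HSC of mouse 1 had 8 Car1 UMIs, and the log2 fold change was -5.07 (SE 0.81). The globin genes Hbb-bs (-3.28), Hba-a1 (-4.11) and Hba-a2 (-2.71) had negative fold changes on kept cells. The mean CPM of Hba-a2 lay the other way, at 12.7 in LT-HSC and 7.49 in ST-HSC, where LT-HSC of mouse 1 had 3 UMIs. The 3 genes changed sign with all barcodes of LT-HSC of mouse 1 (2.79, 2.70 and 4.26) and did not pass there. On those barcodes Hba-a2 passed, higher in LT-HSC, with the mouse as a block, and the 3 genes did so without any 1 of the other libraries. Among 42 S phase genes 0 passed (camera adjusted p = 0.0923), and among 49 G2 and M phase genes 2 rose in LT-HSC, Nusap1 (0.81, SE 0.24) and Cdk1 (0.66, SE 0.21; camera adjusted p = 0.431). Of 14 quiescence genes 1, Trp53inp1, rose in ST-HSC (-0.81, SE 0.24; camera adjusted p = 0.561). Its mean CPM lay the other way, at 22.3 in LT-HSC and 21.6 in ST-HSC, where LT-HSC of mouse 1 had 4 UMIs. Without LT-HSC of mouse 2, Nusap1 (-0.40) and Trp53inp1 (0.59) changed sign. With the mouse as a block, the S phase genes Rad51ap1 and Exo1 and the G2 and M phase genes Kif11 and Mki67 passed, higher in LT-HSC, and Trp53inp1 did not pass. Of these 4 cycle genes, Rad51ap1 passed in the block with all barcodes of LT-HSC of mouse 1 too, and Trp53inp1 passed there. By mean CPM on kept cells, Rad51ap1 (7.86 in LT-HSC and 9.19 in ST-HSC) and Mki67 (21.8 and 23.6) lay the other way. LT-HSC of mouse 1 had 0 and 1 UMIs of them. Of 22 interferon response genes Iigp1 rose in LT-HSC (0.77, SE 0.18) and Ifi27l2a in ST-HSC (-2.71, SE 0.28; camera adjusted p = 0.173). No member passed in the lists of MHC class II and dendritic genes (camera adjusted p = 0.309), MHC class I genes (0.945), cytosolic ribosomal protein genes (0.309), mitochondrially encoded genes (0.184), glycolysis genes (0.890), ribosome biogenesis and Myc target genes (0.890), chaperone genes (0.697), lysosome genes (0.744) and macrophage markers (0.309). Median and mean log2 fold changes differed in sign for MHC class II (0.083 and -0.13), MHC class I (-0.072 and 0.0031), interferon response (0.075 and -0.074) and chaperone genes (0.016 and -0.0067). With the mouse as a block, H2-DMa of the MHC class II list and Ndufa4 of the oxidative phosphorylation list passed, both higher in ST-HSC.

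The second comparison asked how far single cells of the gates lie apart when the genes are chosen in the other animal. Cells of LT-HSC scored above cells of ST-HSC with an area under the receiver operating characteristic curve of 0.944 in held-out mouse 1 (22 LT-HSC and 2633 ST-HSC cells) and 0.849 in held-out mouse 2 (1217 and 1707 cells). The mean was 0.897 ± 0.0666 (SD, n = 2). Under the stricter cell filter the area in mouse 2 was 0.721 and the mean 0.855 ± 0.190 (SD, n = 2), and with genes chosen on all barcodes of LT-HSC of mouse 1 the area in mouse 2 was 0.910. Over 1000 random gene lists the highest area was 0.711 and 0.570. In mouse 2, 5.67% of LT-HSC cells scored below the ST-HSC median and 6.27% of ST-HSC cells above the LT-HSC median. No p is given, since cells are not replicates. Across 6258 genes the LT-HSC minus ST-HSC log2 fold in mouse 1 and in mouse 2 had a Pearson correlation of 0.339 and a Spearman correlation of 0.207, and genes are not independent replicates. Among 1351 genes with a mean of 100 CPM or more, the Pearson correlation was 0.522. It was 0.384 at 20 CPM or more and 0.225 at 100 CPM or more with all barcodes of LT-HSC of mouse 1.

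**Figure D4:**
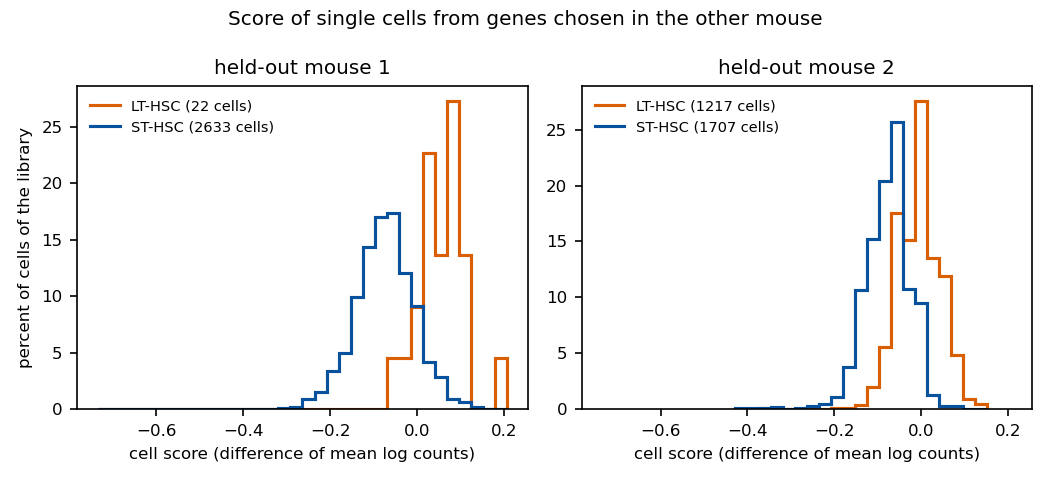
Percent of cells of a library (vertical axis) by cell score (horizontal axis, difference of mean log counts) for LT-HSC and ST-HSC of each held-out mouse. The area under the curve was 0.944 for mouse 1 and 0.849 for mouse 2.

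The third comparison concerned cycling and other cell types. At 2000 UMIs per cell, a UMI of Mki67 or Top2a, genes of dividing cells, was found in 6.74% of LT-HSC cells of mouse 2 (82 of 1217, interval 5.39 to 8.29%), 7.33% of ST-HSC cells of mouse 1 (193 of 2633, 6.36 to 8.39%) and 4.34% of ST-HSC cells of mouse 2 (74 of 1707, 3.42 to 5.41%). In LT-HSC of mouse 1 it was 2 of 22 cells (9.09%, 1.12 to 29.2%). The random draw adds to this: the exact expectations over draws were 6.57%, 7.42%, 4.91% and 5.38% in the same order. Without thinning the shares were 18.0%, 22.1%, 13.1% and 9.09%, and no cells were left out by depth. At the same 2000 UMIs, 1 of 49 cells in the cluster with macrophage markers (2.04%) and 176 of 5129 cells in clusters without a name (3.43%) had such a UMI, against 5 of 37 in the neutrophil-lineage cluster (13.5%) and 169 of 364 in the cycling clusters (46.4%). Mki67 and Top2a were among the markers that named the cycling clusters, so the contrast between cycling and unnamed clusters follows from the naming. The ST-HSC libraries lay on both sides of LT-HSC of mouse 2, and 2 libraries against 2 cannot reach p under 0.05 in an exact permutation test. Within mouse 2 the share was higher in LT-HSC, in the draw and in expectation (6.57% against 4.91%). Within mouse 1 the draw put LT-HSC higher, on 2 of 22 cells, and the expectation put it lower (5.38% against 7.42%). Cells in clusters with markers of other types made up 0.904% of LT-HSC of mouse 2 (11 of 1217, 0.452 to 1.61%), 1.37% of ST-HSC of mouse 1 (36 of 2633, 0.959 to 1.89%), 2.28% of ST-HSC of mouse 2 (39 of 1707, 1.63 to 3.11%) and 0 of 22 cells in LT-HSC of mouse 1 (0 to 15.4%). Of these, 9, 23 and 17 cells lay in a cluster with macrophage markers, whose HSC markers were at the level of the other cells (median log2 ratios of 0.18, 0.016 and -0.11), so whether they are another cell type is open.

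The last comparison set the animals against each other. Between mouse 1 and mouse 2, edgeR called 0 of 12656 genes, with 240 at an unadjusted p under 0.05. DESeq2 was not run on this comparison. That fit counts the gate difference as residual spread, so a count of 0 does not show that the mice are alike. The clusters parted the ST-HSC cells by mouse: 1 cluster held 809 cells of mouse 1 and 15 of mouse 2, and another 11 and 650. Differences between animals and between library preparations cannot be told apart here. With the gate and the mouse in the same fit, as a block, edgeR called 118 genes, 95 higher in mouse 2 and 23 higher in mouse 1. Without LT-HSC of mouse 2 it called 31 genes, and without ST-HSC of mouse 2 it called 490; there 1 mouse is left with 1 gate, so gate and mouse cannot be told apart in these counts. The neutrophil gene S100a8 was the 1 gene called under the stricter cell filter, higher in mouse 1 (mouse 2 minus mouse 1: -4.60, SE 0.40). On kept cells it was higher in ST-HSC of mouse 2, at 872 against 231 CPM; the stricter filter left 85 of its 11470 UMIs in ST-HSC of mouse 2 and 3841 of 6387 in ST-HSC of mouse 1.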

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

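The tests of RNA of other cells and of free RNA were chosen after the result had been seen. In that library 99.2% of UMIs (99.1506%) lay in barcodes outside the kept cells, a signal the comparisons on kept cells leave out. Those barcodes held Slamf1 at 12.9 CPM (12.8528), above the floor of 3 counts.

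The pattern is that this library spreads 13575402 UMIs over 39553 barcodes. The values argue against RNA mainly of other cells. For 101 genes higher in LT-HSC of mouse 2, called without this library, its median log2 ratio to LT-HSC of mouse 2 was -0.27 (bootstrap SD 0.038). ST-HSC lay at a median of -0.98 to LT-HSC of mouse 2. Globin genes went the other way, at 0.159% of UMIs against 0.0126% in LT-HSC of mouse 2. So did the neutrophil genes Camp (63.3 CPM against 0.539), Ngp (27.8 against 1.39) and Elane (5.60 against 0.154). Mpo (0.659 against 0.462) and Ctsg (0.165 against 0.385) stayed low. A small share of RNA of other cells is therefore not excluded. Whether the barcodes may be shallow samples of intact cells or free RNA of the sorted LT-HSCs could not be told apart by the spread of counts between barcodes. That test does not use the number of barcodes. LT-HSC of mouse 2 held a similar total, 13339226 UMIs, over 1288 barcodes. The excess spread of counts between barcodes was 472% of that in LT-HSC of mouse 2 at 200 UMIs, with an SD of 227, and both bounds set for the test lie within 2 SD. A look taken afterwards showed 1 barcode carrying much of it (index 1.14, and 1.08 without it, against 1.03 in mouse 2), led by Hbb-bs. The median index over genes was 1.021, against 1.023 in mouse 2. The bounds were set on the mean index and no spread was computed for the median, so no conclusion is drawn from it.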

How the results depend on the processing

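The alternatives that use all or only the outside barcodes of LT-HSC of mouse 1, all barcodes of every library, crossed mouse numbers and the expected cycle shares were chosen after the data had been seen. Over the other alternatives, 74 of 99 summary values stayed within the bounds set for them (1.5 times for a count, 1 SD or the 95% interval for a value with no test), and 38 of 48 did so over those chosen afterwards. The counts of 455 and 396 genes were 96 and 92 when only genes with a mean of 20 CPM or more were tested (6258 genes), 167 and 155 with cells thinned to 2000 UMIs, and 8 and 15 with 22 cells per library. DESeq2 called 28 and 24. The setting with 22 cells per library leaves 3672 genes to test, and the thinned one 10687. Of the 24 genes with the largest fold changes, Mtss1l lost its call when only genes of 20 CPM or more were tested. Camp, Ngp and Lcn2 lost theirs under robust shrinkage in edgeR. With 22 cells per library 9 of the 24 could be tested, and Cracr2b, Tgm2 and Bex4 lost their calls. The cause of the difference between the tools was not tested. With 1 library left out in turn, on kept cells or on all barcodes of LT-HSC of mouse 1, the counts ranged from 1 to 604 and from 0 to 536; the lowest were without LT-HSC of mouse 2, when the LT-HSC arm is 22 cells. With that arm as all barcodes instead, the counts without LT-HSC of mouse 2 were 567 and 536. A lone library is assumed to vary like the other group. The floor of 26.0 CPM in LT-HSC of mouse 1 limits what its kept cells can show for genes below it.

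With the mouse number as a replicate block the counts were 448 and 408, and with all barcodes of LT-HSC of mouse 1 the paired counts were 849 and 628. Between the mice the block gave 118 genes, and 102 with all those barcodes, against 0 without it. The block removes the gate difference from the residual spread, which the fit without it holds. On kept cells it moved both gate counts by less than 1.5 times. On all those barcodes, crossing the numbers of the LT-HSC libraries gave 522 and 414 genes in place of 849 and 628, and 1 gene between the mice, Lcn2. Between the mice, the stricter cell filter gave 1 gene and thinning 38, and leaving out 1 library gave 0 to 490, in fits where 1 mouse is left with 1 gate, so that gate differences count as mouse differences; with all barcodes and without LT-HSC of mouse 2, the 1 gene was Fbp1. Of 12 lists past camera, 0 passed with an estimated correlation and 0 with fry; with all barcodes of LT-HSC of mouse 1 these were 0 and 5. The mean area under the curve was 0.817 with 20 genes per direction. Leaving out the gate genes moved nothing, since none was among the genes chosen, so that setting tests nothing. The correlation of folds was 0.313 over genes of 5 CPM or more and 0.522 over genes of 100 CPM or more; with all barcodes of LT-HSC of mouse 1 it was 0.384 at 20 CPM, 0.505 at 5 CPM and 0.225 at 100 CPM. The share of cells with a cycle gene UMI was 18.0% in LT-HSC of mouse 2, 22.1% in ST-HSC of mouse 1 and 13.1% in ST-HSC of mouse 2 without thinning, where deeper cells have more UMIs to find. In ST-HSC of mouse 2 it was 6.03% under the looser filter, which adds 2 cells; the expected share over draws was 4.91% under both filters with an SD of 0.375 between draws, so this draw lay far above its expectation and the one on kept cells below. In LT-HSC of mouse 1 the stricter filter left 7 cells and 0%.

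Among genes and lists past the threshold on kept cells, the sign changed under some alternative for the globin genes Hba-a1, Hbb-bs and Hba-a2, for Gp9, Nusap1, Cdk1, Trp53inp1 and Fos, and for the nuclear oxidative phosphorylation, immediate early and cholesterol synthesis lists. The other sign changes below belonged to genes and lists that did not pass there. Values are log2 fold changes, and medians for lists. With 22 cells drawn from each library the values were Ly6a 0.086, Tap2 0.27, Cdk1 -0.031, Ier3 0.59, Hspd1 -0.042, Insig1 -0.43, Ctsb -0.28, G2 and M phase genes -0.31, immediate early genes 0.19, cholesterol synthesis genes -0.16. With all barcodes of LT-HSC of mouse 1 they were Hba-a1 2.70, Hbb-bs 2.79, log2 fold change of Hba-a2 4.26, Ier3 0.072, mt-Nd4l 0.30, log2 fold change of Dkc1 -0.0051, Hspe1 0.14, Hspa5 0.0096, nuclear oxidative phosphorylation genes 0.10. With only its barcodes outside the filter they were Hba-a1 2.71, Hbb-bs 2.80, log2 fold change of Hba-a2 4.27, Ier3 0.073, mt-Nd4l 0.30, log2 fold change of Dkc1 -0.0095, Hspe1 0.15, Hspa5 0.012, nuclear oxidative phosphorylation genes 0.11. With all its barcodes and the block they were Hba-a1 0.90, Hbb-bs 1.46, log2 fold change of Hba-a2 2.42, Ier3 0.030, mt-Nd4l 0.16, log2 fold change of Dkc1 -0.023, Hspe1 0.13, Hspa5 0.017, nuclear oxidative phosphorylation genes 0.11. With the numbers crossed they were Hba-a1 1.12, Hbb-bs 1.62, log2 fold change of Hba-a2 2.88, Ier3 0.026, mt-Nd4l 0.16, log2 fold change of Dkc1 -0.020, Hspe1 0.13, Hspa5 0.016, nuclear oxidative phosphorylation genes 0.11. With DESeq2 on all its barcodes they were Hba-a1 2.64, Hbb-bs 2.75, log2 fold change of Hba-a2 4.12, Ier3 0.050, mt-Nd4l 0.27, log2 fold change of Dkc1 -0.025, Hspe1 0.12. With all barcodes of every library they were log2 fold change of Hba-a2 0.038, Ier3 0.068, mt-Nd4l 0.22, log2 fold change of Dkc1 -0.0060, Hspe1 0.15, nuclear oxidative phosphorylation genes 0.10. Under the looser cell filter they were Hbb-bs 0.59, log2 fold change of Hba-a2 1.32. With DESeq2 on kept cells they were log2 fold change of Hba-a2 0.53, H2-Eb1 -0.082, H2-Aa -0.015. Without the cycling clusters they were Kif11 -0.091, Mki67 -0.35, G2 and M phase genes -0.21. The cause was not tested, except that leaving out cycling clusters removes cycling cells. With 1 library left out in turn, on kept cells or on all barcodes of LT-HSC of mouse 1, the lowest and highest values were Kit -0.072 to 0.25, Ly6a -0.34 to 0.058, Gp9 -0.36 to 1.75, Hba-a1 -4.89 to 4.47, Hbb-bs -4.19 to 6.01, log2 fold change of Hba-a2 -3.65 to 5.94, H2-Eb1 -2.42 to 0.66, H2-Aa -0.90 to 0.51, H2-DMb1 -0.57 to 0.34, Tap2 -0.43 to 0.12, H2-Q6 -0.24 to 0.46, Rad51ap1 -9.99 to 0.94, Clspn -0.69 to 0.83, Nusap1 -0.40 to 1.22, Mki67 -1.55 to 0.88, Trp53inp1 -0.95 to 0.59, Foxo3 -0.51 to 0.10, Tob1 -0.66 to 0.26, Fos -1.05 to 0.10, Ier3 -0.71 to 0.39, mt-Nd4l -0.51 to 0.80. For the others they were Ndufa4 -0.93 to 0.058, Cox5a -0.97 to 0.17, Ndufb2 -0.996 to 0.15, Atp5f1 -0.82 to 0.11, Pfkp -1.53 to 0.50, Pkm -1.29 to 0.037, log2 fold change of Dkc1 -0.26 to 0.23, Wdr43 -0.30 to 0.22, Bop1 -1.36 to 0.075, Hspe1 -0.64 to 0.32, Hspa5 -1.32 to 0.15, Cct5 -0.018 to 0.36, Hspd1 -0.32 to 0.29, Idi1 -1.14 to 0.63, Insig1 -1.06 to 1.01, Sqle -1.45 to 0.47, camera result of erythroid genes -6.39 to 0.82, S phase genes -0.91 to 0.29, nuclear oxidative phosphorylation genes -0.45 to 0.23, glycolysis genes -0.57 to 0.21, cholesterol synthesis genes -0.80 to 0.37. The lowest value of Rad51ap1 is a fitted value against 0 UMIs and is no bound.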

Other observations

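All tests in this part were chosen after the results had been seen. In the fits with gate and mouse together, 52 genes differed between the mice in the same direction on kept cells and on all barcodes of LT-HSC of mouse 1, 36 higher in mouse 2 and 16 higher in mouse 1. Those fits differ only in that library, so the overlap is no independent check. Leading by p on kept cells were Retnlg (4.16, SE 0.28), a leading gene of the neutrophil-lineage cluster, and the basophil gene Mcpt8 (2.96, SE 0.22), both higher in mouse 2. Prss34, Lcn2 and Ctsg were higher there too. In the gate fit without the clusters of other types, Mcpt8, Prss34, Lcn2 and Ctsg had too few counts to be tested. Enough of their UMIs lay in those clusters, rather than in the remaining cells, to put them under the count filter without them. The fit with gate and mouse together was not run without those clusters. For the other genes, whether neutrophil-lineage and basophil cells rather than the stem cells account for them was not tested. Fbp1, a gluconeogenic enzyme gene, lay at 36.0 and 74.5 CPM in LT-HSC and ST-HSC of mouse 2 and at 5.52 and 10.6 CPM in mouse 1 (all barcodes for LT-HSC). Hist1h2ap, a histone gene, was lower in mouse 2, at 26.7 and 19.8 CPM against 112 and 83.9 CPM. Nme2, a nucleoside diphosphate kinase gene, lay at 24.7 and 16.8 CPM against 105 and 64.1 CPM. Hist1h2ap and Nme2 have close relatives in the genome, so their counts are uncertain.

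The granule genes higher in ST-HSC raise the question of whether neutrophil-lineage cells passed the gate. RNA of Camp and Ngp was not confined to ST-HSC, since all barcodes of LT-HSC of mouse 1 held them at 63.3 and 27.8 CPM. Mpo lay at 0.659 CPM there. In ST-HSC of mouse 1 and mouse 2, the 13 and 22 cells of that cluster held 58.0% and 81.1% of the UMIs of 12 granule genes, and 96.1% and 98.6% without Prtn3, which other ST-HSC cells held at 426 and 445 CPM. The cluster held S100a8 at 27073 and 47547 CPM. Its HSC markers lay at median log2 ratios of -4.20 and -4.29 to the other cells, so such cells are a candidate source of these UMIs. Free RNA of those cells does not account for Mpo in the remaining cells, where Mpo to S100a8 was 7.20 and 17.2 times the ratio in the cluster; for Elane it was 0.766 and 1.85 times, and free RNA may be its source there. The sort for lineage-negative cells would remove mature neutrophils, and no biological explanation was tested.

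RNA of the complement genes C1qa, C1qb and C1qc, products of macrophages, was found in 207 of 5557 cells of the 3 deep libraries. For 49 of these, with 2 or 3 of the genes, free RNA spread over droplets is argued against, since they were 10.9 times the 4.51 cells that independence gives. For the 158 cells with 1 of the genes, free RNA stays open. In the cluster with macrophage markers (49 cells, 32 of them with 2 or 3 of the genes), a whole macrophage joined to a stem cell in 1 droplet is argued against: its HSC markers had a lowest median log2 ratio of -0.11 (-0.108) to other cells, and UMIs per cell were 0.956 to 1.03 times theirs. A part of a macrophage on a stem cell, or expression by the stem cells themselves, may remain, and neither was tested.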
